A study of Mus musculus with 8 samples.

How the data were processed

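RNA was measured by bulk RNA-seq in 8 samples of cultured mouse alveolar macrophages, 2 in each of 4 groups: vehicle, MSDC, Poly(I:C) with vehicle and Poly(I:C) with MSDC. The table deposited by the authors gives for each gene and sample an expected count, an FPKM and a TPM. The expected counts are read counts per the file headers, are not scaled to depth and are partly not whole, and how the authors made them is not given in the sources used here. The FPKM values, named so per the file headers, are proportional to the counts within a gene and were scaled by the authors to gene length and depth in a way not given in the sources used here. The TPM values deposited beside them, named so per the file headers, sum to the same total in each sample and were not used here. The submitters' processing notes name TopHat2 2.1.1, Bowtie2 2.3.4, Cuffdiff and the mouse genome GRCm38 (mm10), without saying which of these made which column.

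The table held 15521 genes, of which 593 had no count in any library, and 15419 gene identifiers (99.3%) were found in the RefSeq annotation of GRCm38. Gene symbols that had been turned into dates (23) were repaired from the gene identifiers. Between 5.95 and 7.19% of the values in a library, out of all genes with zeros counted as whole, were not whole numbers, and all were rounded. Libraries held 28762425 to 29493223 counts, and 12904 to 13281 genes were above 0 in a library. The 10 most abundant genes took 11.6 to 12.8% of a library. A floor of 3 counts is 0.102 to 0.104 CPM per library.

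The test was chosen before the data were examined, with limma planned for FPKM and edgeR planned for counts, and the edgeR plan was used because the table holds counts. Genes were filtered with filterByExpr, which kept 11621, libraries were scaled by TMM (factors 0.985 to 1.027), and 1 quasi-likelihood model with the 4 groups as terms was fitted to all 8 libraries (edgeR 4.0.16 in R 4.3.3, 4 residual degrees of freedom, common dispersion 0.00383, prior degrees of freedom 10.8). The 5 comparisons were Poly(I:C) in vehicle, Poly(I:C) in MSDC, MSDC without Poly(I:C), MSDC with Poly(I:C), and their interaction, which is positive where the response to Poly(I:C) is larger in MSDC. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison, two-sided. Replicate numbers do not pair the samples: over the 6 pairs of groups the correlations of replicate differences ranged from -0.026 to 0.034, so no pairing was used.

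Gene lists were written before the data were examined. They cover interferon-stimulated genes, interferons, RNA sensing, cytokines and mediators, chemokines, NF-kB targets, inflammasome, MHC class I and II presentation, alternative activation, alveolar macrophage identity, mitochondrial pyruvate handling, PPAR targets, cholesterol synthesis, LXR targets and fatty acid synthesis, glycolysis, HIF-1 targets, TCA cycle, oxidative phosphorylation, fatty acid oxidation, integrated stress response, NRF2 targets, unfolded protein response, heat shock and immediate early genes, lysosome, cell cycle, ribosomal proteins, mitochondrially encoded genes and markers of 8 kinds of other cells. The table held 0 mitochondrially encoded genes of that list. Some lists share members, so their tests are not independent. The PPAR targets share Fabp1, Fabp4, Cidec and Lpl with the identity list and Pdk4 with pyruvate handling. They share Cpt1a, Acadl, Hadha and Acaa2 with fatty acid oxidation. Lists with at least 4 tested genes were compared with all other tested genes by camera (limma 3.58.1) with its preset correlation of 0.01, adjusted by Benjamini-Hochberg over 150 tests, with camera with an estimated correlation and fry beside it. Camera called 44 of the 150, camera with an estimated correlation 8 and fry 65.

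Genes are named in the text by a rule fixed before the data were examined. It takes, for each comparison, the 8 largest rises and 8 largest falls among called genes whose 2 groups do not overlap and whose higher group averages at least 5 CPM, leaving out predicted models, up to 4 members with the smallest p of each list described, and a fixed set (Mpc1, Mpc2, Ifnb1, Il6, Tnf, Il1b, Ccl2, Cxcl10, Isg15, Hif1a, Acod1, Pparg and Pdk4). The overlap condition does not apply to the interaction. The report prints part of the genes so named, some are not reported here, and genes outside the rule are said to have been chosen after their values were seen. Ratios against groups at 0 use a floor of 3 counts over the group, and ratios against 1 to 3 counts carry a 95% counting interval.

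The procedure was tested on simulated data in which 200 of 11621 genes had been changed. In the comparison of MSDC with Poly(I:C) it recovered 65.7, 88.1 and 95.5% of genes changed 1.5-, 2- and 4-fold and called 7 unchanged genes, and in the interaction it recovered 46.3, 82.1 and 92.4% and called 8. In a comparison left unaltered it called 0 genes with edgeR and with limma, and 2 with DESeq2, and camera called 0 of 50 lists of unchanged genes. The simulated genes varied independently, so the list result does not cover lists whose genes are correlated. Alternatives tried were the fit without a filter, a filter of 5 CPM in at least 2 samples, DESeq2's size factors, a replicate block, the DESeq2 1.42.0 Wald test, the groups of a comparison alone, a fold threshold and leaving out each library. Limma on log2 FPKM and scaling by library totals alone were added after seeing the data.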

Results

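Alveolar macrophages, the resident phagocytes of the airspaces, had been collected from mouse lungs by lavage, purified by adherence for 2 h and cultured with GM-CSF at 10 ng/ml, a growth factor on which these cells depend. They received vehicle (DMSO) or MSDC at 10 µM for 2 h and were then left unstimulated or were stimulated with Poly(I:C) at 5 µg/mL (for 24 h per the sample labels, overnight per the series description), a synthetic double-stranded RNA used as a mimic of viral RNA. MSDC is the prefix of code-named compounds known to act on the mitochondrial pyruvate carrier, and the labels do not say which member was used. The 8 bulk RNA-seq libraries form 4 groups of 2. Each library held 28762425 to 29493223 estimated counts over 15521 genes, of which 11621 were tested. A floor of 3 counts corresponds to 0.102 to 0.104 CPM (counts scaled to the library total) per library, which covers counting error only. The labels do not say whether the samples of a group came from separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical. Levels are given as mean CPM ± SD (n = 2), with library totals adjusted by the TMM factors. Changes are given as log2 fold changes with a standard error (SE). This SE was derived from the change and the F statistic of its test, so it may misstate the uncertainty of genes with few counts.

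Across all tested genes the 4 groups were separated, with 50% of the variance on the first principal component and 30.3% on the second. The lowest correlation of log2 CPM within a group was 0.9899 and the highest between groups was 0.9769. No replicate pair agreed within sampling noise. The chi-square statistic per degree of freedom between replicates was 15.2 for vehicle, 4.35 for MSDC, 6.41 for Poly(I:C) with vehicle and 6.49 for Poly(I:C) with MSDC. The fit shares its estimate of spread across the 4 groups, so the vehicle libraries also weigh on the p-values of comparisons without them. That shared spread may be too small for the vehicle group itself.

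The first comparison asked what Poly(I:C) changed in cells given vehicle. The antiviral program rose: all 26 tested interferon-stimulated genes were higher, with a median log2 fold change of 5.34. Ifit2, which encodes an RNA-binding antiviral protein, went from 1.58 ± 0.458 to 221.5 ± 11.8 CPM, and Zbp1, a sensor of Z-form nucleic acids, from 17.2 ± 0.321 to 221.4 ± 0.611 CPM. Oasl1 rose by 9.15 (SE 0.19, adjusted p = 4.3e-14) and Isg15, a ubiquitin-like modifier, by 6.09 (SE 0.19). Inflammatory mediators rose beside them, led by Acod1, the enzyme that makes itaconate, from 5.17 ± 0.204 to 73.8 ± 7.61 CPM. Genes of cholesterol synthesis fell together, 16 of 22, with Sc5d going from 25.4 ± 1.27 to 15.2 ± 0.567 CPM.

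In total 874 genes were higher and 477 lower (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), of which 293 and 12 changed at least 2-fold. The largest rises belonged to interferon-inducible families. Apol9b and Ifi213 had no count in the vehicle libraries and were at least 249-fold and at least 151-fold higher, against a floor of 3 counts over the group. Ifit3b, Ifi208 and Ms4a4c had 1 or 2 counts there, and their ratios were 868 (95% counting interval 240 to 7170), 719 (129 to 28400) and 523 (93.5 to 20700). Ifit3 rose by 9.22 (SE 0.24; 10.78 without vehicle replicate 1, 8.46 without vehicle replicate 2) and Ifi206 by 8.73 (SE 0.31; 9.96 and 8.05 in the same order). The values of Ifit3 and Ifit3b, of Apol9b and of the Ifi200 genes are uncertain in their split, because their sequences resemble those of neighbours and 5.95 to 7.19% of the deposited values were not whole. The largest falls were smaller. The adhesion receptor gene Adgrg1 fell by 1.15 (SE 0.22), Ptgs1, which encodes cyclooxygenase-1, by 0.98 (SE 0.17), the kinase gene Dgkg by 0.96 (SE 0.19), and the keratin gene Krt19 by 0.95 (SE 0.11). Ceacam1, Slc46a3, Cald1 and Ifi27 fell by 0.88, 0.86, 0.86 and 0.86.

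By list, 9 of 12 genes of RNA sensing rose, among them Ddx58 (2.94, SE 0.13), Dhx58 (2.96, SE 0.12) and Ifih1 (2.15, SE 0.09), the RIG-I-like receptors, and Tlr3 (1.87, SE 0.12). All 13 genes of MHC class I presentation rose, such as the peptide transporter gene Tap1, from 40.8 ± 1.86 to 201 ± 9.34 CPM, and Nlrc5 (2.68, SE 0.13), a transactivator of class I genes. Of 9 class II genes 6 rose, H2-Ab1 by 0.71 (SE 0.08) and Cd86 by 1.16 (SE 0.21). Of 15 chemokines 10 rose (12 adjusted over the list alone), Ccl5 by 5.12 (SE 0.30; 5.78 without vehicle replicate 1), Cxcl10 by 4.95 (SE 0.50) and the monocyte attractant Ccl2 by 2.31 (SE 0.14). Of 12 cytokines and mediators 7 rose and 1 fell (9 and 1 adjusted over the list alone), with Il1b rising by 1.49 (SE 0.18) and Tnf by 0.67 (SE 0.10). Of 11 inflammasome genes 6 rose and 1 fell (7 and 1 adjusted over the list alone), with Casp4 rising by 1.15 (SE 0.11). Ifnb1 held 3 counts in 1 stimulated library and 0 in the other 7, and Il6 held at most 4 counts in any library, so neither was tested.

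Each of these lists stood apart from the other genes by camera with its preset correlation, with adjusted p of 7.2e-290 for the interferon-stimulated genes, 6.0e-60 for class I, 1.4e-14 for RNA sensing, 3.0e-13 for chemokines, 9.4e-09 for cholesterol synthesis, 3.7e-06 for cytokines, 0.00131 for the inflammasome and 0.00286 for class II. With an estimated correlation only the interferon-stimulated genes (adjusted p = 0.0177) and class I (adjusted p = 0.0302) kept the call, and the others had adjusted p = 0.0862 for RNA sensing, 0.0785 for chemokines and for cytokines, 0.139 for the inflammasome, 0.16 for class II and 0.167 for cholesterol synthesis with an estimated correlation. The balance of the calls depended on the scaling, since 64.7% of called genes were higher in the fit used here and 45.7% (729 higher, 867 lower) when libraries were scaled by their totals alone, which moved the median of all genes by -0.0545. The 477 lower genes became 210 without replicate 1 of Poly(I:C) with vehicle, 257 when these 2 groups were fitted alone and 751 with limma on log2 FPKM.

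The second comparison asked what Poly(I:C) changed in cells given MSDC. The interferon program rose here as well, with 25 of 26 interferon-stimulated genes higher (26 adjusted over the list alone) and a median of 6.12. Rsad2, which encodes the antiviral enzyme viperin, went from 0.186 ± 0.215 to 120.5 ± 0.274 CPM and rose by 9.29 (SE 0.25), Ifit1 rose by 8.46 (SE 0.29), Cmpk2 by 8.14 (SE 0.32), Usp18 by 7.95 (SE 0.27) and Oas2 by 7.94 (SE 0.37). These genes stood at 0.186 to 0.355 CPM with MSDC alone. Without MSDC replicates 1 and 2 the values were 8.46 and 11.59 for Rsad2 and 7.66 and 10.45 for Ifit1. They were 7.24 and 11.36 for Cmpk2 and 6.98 and 13.76 for Usp18. Ifit1bl1 was at least 153-fold higher against a floor of 3 counts, and Ifit3b had a ratio of 551 (152 to 4560). Acod1 rose by 2.29 (SE 0.12) and Ccl2 by 1.59 (SE 0.23; 2.28 without MSDC replicate 2), while Tnf (0.06, SE 0.10, adjusted p = 0.843) and Il1b (0.66, SE 0.21, adjusted p = 0.0977) were not called. Among the falls were the lipid enzyme genes Scd1 (-0.64, SE 0.09) and Mvd (-0.63, SE 0.07), the ligand gene Ulbp1 (-0.78, SE 0.09) and Rhof (-0.57, SE 0.10).

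In total 560 genes were higher and 174 lower, 230 and 2 of them at least 2-fold. This comparison holds no vehicle library, but its spread was estimated over all 8 libraries. All 13 class I genes rose (Tap1 2.37, SE 0.07), as did 8 of 12 RNA sensing genes (Dhx58 3.94, SE 0.13), 8 of 15 chemokines (11 adjusted over the list alone; Ccl5 3.47, SE 0.33, and Cxcl10 4.77, SE 0.47) and 5 of 9 class II genes (H2-Ab1 0.80, SE 0.09). Without MSDC replicates 1 and 2 the values were 2.85 and 4.59 for Ccl5 and 3.90 and 7.40 for Cxcl10. Of 22 cholesterol synthesis genes 15 fell (19 adjusted over the list alone), such as Sc5d (-0.55, SE 0.08) and Fdft1 (-0.50, SE 0.07). The camera adjusted p were 0 (under the smallest number the software holds) for interferon-stimulated genes, 2.1e-56 for class I, 1.5e-22 for RNA sensing, 6.3e-10 for cholesterol synthesis, 3.7e-06 for chemokines and 0.0167 for class II. With an estimated correlation they were 0.0177, 0.0388, 0.0785, 0.16, 0.169 and 0.196 in the same order, so that the last 4 lists lost the call. The 174 lower genes became 331 and 421 without vehicle replicates 1 and 2, 50 and 63 without MSDC replicates 1 and 2, 77 and 54 without replicates 1 and 2 of Poly(I:C) with MSDC, 415 when these 2 groups were fitted alone and 298 without the expression filter. The higher genes were 351 without MSDC replicate 2. The falls of Zdhhc2, Tspan32 and Gpx3, among the 8 largest, lost the call without at least 1 library.

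Both responses to Poly(I:C) shared 485 of the 874 genes higher in vehicle and 107 of the 477 lower, against 42 and 7 for independent lists of these sizes, and 1 and 2 genes went opposite ways. The fold changes correlated across 11621 genes with Pearson's r = 0.762 and Spearman's rho = 0.49, where genes are not independent replicates. These 2 comparisons share no library.

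The third comparison asked what MSDC changed in unstimulated cells. Most PPAR targets and cholesterol synthesis genes and some genes of pyruvate handling rose, and all class II genes and several chemokine genes fell. Of 16 PPAR targets 13 rose and 1 fell (14 and 1 adjusted over the list alone), with Plin2, which coats lipid droplets, going from 629.6 ± 44.1 to 2777 ± 57.2 CPM and Cd36, a fatty acid receptor, from 681.3 ± 50.1 to 2783 ± 77.8 CPM. Mpc2, a subunit of the mitochondrial pyruvate carrier, went from 24.1 ± 0.962 to 96.9 ± 8.09 CPM, its partner Mpc1 from 178.2 ± 2.54 to 255.6 ± 14.5 CPM, and Pdk4, a kinase that inhibits pyruvate dehydrogenase, from 0.386 ± 0.0314 to 11.0 ± 0.674 CPM. All 9 MHC class II genes fell, H2-Ab1 by 1.61 on the log2 scale (SE 0.09) and the invariant chain gene Cd74 from 575.2 ± 4.25 to 263.4 ± 1.26 CPM. Ccl2 fell by 3.15 (SE 0.20; -3.85 without MSDC replicate 2) and Ccl17 by 2.79 (SE 0.10).

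MSDC alone was associated with 1294 genes higher and 1440 lower, 258 and 377 of them at least 2-fold, and leaving out MSDC replicate 1 gave 849 higher. The largest rises were Cyp4a12b (7.20, SE 0.37; 8.13 without vehicle replicate 1) and Cyp4a12a (5.56, SE 0.20), cytochrome P450 genes of fatty acid hydroxylation, C5ar1 (6.38, SE 0.16), the receptor for complement fragment C5a, Lad1 (5.82, SE 0.24), Acaa1b (5.66, SE 0.10), a peroxisomal thiolase, Pitpnm2 (5.19, SE 0.13), Pdk4 (4.82, SE 0.27) and Fabp1 (4.29, SE 0.20), a fatty acid binding protein. The call of Rtp4 was lost with DESeq2 (adjusted p from 4.79e-67 to 0.0571 over the alternatives). Cyp4a12a and Cyp4a12b are near-identical, and Acaa1b and Ear1 have close relatives, so reads could be split between copies. The largest falls were Arl4c (-3.84, SE 0.19), Rnase2a (-3.61, SE 0.23), Hpse (-3.48, SE 0.19), Ms4a6c (-3.23, SE 0.19), Slfn5 (-3.15, SE 0.40), Rtp4 (-3.15, SE 0.58), Ccl2 (-3.85 without MSDC replicate 2) and Fcgr2b (-3.06, SE 0.12), the inhibitory Fc gamma receptor. Slfn5 stood at 21.7 and 7.86 CPM in the vehicle replicates and its value was -2.25 without vehicle replicate 1. That of Rtp4 was -2.05 and -3.77 without vehicle replicates 1 and 2 and -2.23 and -6.64 without MSDC replicates 1 and 2.

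Among metabolic lists, 20 of 22 cholesterol synthesis genes rose (21 adjusted over the list alone), Hmgcs1 by 1.46 (SE 0.08) and Fdft1 by 1.10 (SE 0.08). Of 15 genes of fatty acid oxidation 12 rose and 1 fell, with Acaa2 rising by 1.13 (SE 0.08) and Cpt1a, the mitochondrial carnitine palmitoyltransferase, by 0.66 (SE 0.06). Of 15 genes of mitochondrial pyruvate handling 7 rose and 1 fell, with Pcx, which encodes pyruvate carboxylase, rising by 0.75 (SE 0.09). The PPAR targets included Cidec (3.49, SE 0.08) and Angptl4 (3.06, SE 0.08), while Pparg itself fell by 0.65 (SE 0.06). Of 24 alveolar macrophage identity genes 11 rose and 8 fell. Their median was 0.03, and -0.01 with scaling by library totals alone, while their mean was 0.78, with Fabp1 (4.29, SE 0.20), Krt79 (3.85, SE 0.10), Ear1 (3.78, SE 0.07), Cidec and Krt19 (2.69, SE 0.09) among the members that rose. Fabp1 and Cidec, like Fabp4 and Lpl, are also in the PPAR target list, so the calls of these lists are not independent. In the alternative activation list, 6 of 9 genes fell and 1 rose, with Chil3 falling by 0.82 (SE 0.05) and Socs2 by 1.06 (SE 0.09). Of 15 chemokines 6 fell and 1, Ccl9 (1.05, SE 0.06), rose. Other inflammatory lists were not called by camera: 3 cytokines and mediators rose and 2 fell of 12 (adjusted p = 0.571), 5 inflammasome genes rose and 4 fell of 11 (adjusted p = 0.514), and 2 NF-kB targets rose and 5 fell of 15 (adjusted p = 0.647). Of 13 class I genes 8 fell (9 adjusted over the list alone), among them Nlrc5 (-1.37, SE 0.16), and H2-D1 rose (0.44, SE 0.05). Of 26 interferon-stimulated genes 14 fell (16 adjusted over the list alone), among them Ifi204 (-2.22, SE 0.16), Oas1a (-1.46, SE 0.13) and Xaf1 (-2.69, SE 0.31), with a list median of -0.68.

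Camera adjusted p were 2.1e-48 for PPAR targets, 3.9e-20 for class II, 4.8e-19 for cholesterol synthesis, 1.2e-13 for alveolar macrophage identity, 6.8e-08 for fatty acid oxidation, 1.0e-05 for alternative activation, 4.0e-05 for interferon-stimulated genes, 8.1e-05 for chemokines, 0.000279 for pyruvate handling and 0.0165 for class I. With an estimated correlation PPAR targets and class II kept the call (adjusted p = 0.0177 each), and the others had adjusted p = 0.0785 for cholesterol synthesis, identity and alternative activation, 0.202 for fatty acid oxidation and chemokines, 0.164 for pyruvate handling, 0.691 for class I and 0.725 for interferon-stimulated genes with an estimated correlation. The interferon-stimulated genes differed between the vehicle replicates: Irf7, shown after its values were seen, stood at 15.5 and 6.24 CPM in them and at 1.69 and 4.22 CPM with MSDC. Without vehicle replicate 1 the list median was -0.28 (9 lower, 1 higher), without MSDC replicate 1 it was -0.46 (9 lower, 2 higher) and without MSDC replicate 2 it was -1.45 (15 lower).

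The fourth comparison, of MSDC with vehicle in stimulated cells, asked which genes of Poly(I:C)-treated macrophages the compound changed. Some of the mediators induced by Poly(I:C) were lower and some were not. Acod1 fell from 73.8 ± 7.61 to 20.3 ± 1.00 CPM, Ccl2 from 76.3 ± 0.566 to 5.25 ± 0.0598 CPM, Il1b from 11.8 ± 0.755 to 4.11 ± 1.10 CPM and Tnf from 24.4 ± 0.227 to 15.9 ± 0.475 CPM, whereas Il1rn, chosen after its values were seen, was at 205.1 ± 16.9 and 194.2 ± 10.7 CPM (-0.08, SE 0.09, adjusted p = 0.581). Of the 12 cytokines and mediators 6 were lower and 2 higher, and camera did not call the list (adjusted p = 0.0865, and 0.388 with an estimated correlation). The interferon-stimulated genes were split, with 15 of 26 lower and 0 higher (edgeR), a median of -0.37 and 11 not called; DESeq2 gave 9 lower and 0 higher. Ifi205 fell by 2.17 (SE 0.22) and Ifi204 by 1.03 (SE 0.10), whereas Rsad2, chosen after its values were seen, differed by 0.05 (SE 0.11, adjusted p = 0.792) and Cxcl10 by 0.19 (SE 0.30, adjusted p = 0.703). The call of Isg15 (-0.38, SE 0.13, adjusted p = 0.0346) was lost in 5 of 16 alternatives, with adjusted p up to 0.614. All 9 class II genes fell again, and most PPAR targets and 8 of 15 genes of pyruvate handling were higher, with Plin2 at 710.5 ± 1.05 and 2770 ± 89.9 CPM and Mpc2 at 26.7 ± 1.94 and 104.7 ± 7.75 CPM.

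In total 1450 genes were higher and 1586 lower, 279 and 399 of them at least 2-fold. The largest rises were C5ar1 (6.74, SE 0.17), Cyp4a12a (5.58, SE 0.19), Acaa1b (5.55, SE 0.10), Lad1 (5.43, SE 0.26), Cyp4a12b (5.36, SE 0.28), Pitpnm2 (5.02, SE 0.13), Gpd1 (4.36, SE 0.09), which encodes glycerol-3-phosphate dehydrogenase, and Pdk4 (4.28, SE 0.25). Without replicate 2 of Poly(I:C) with vehicle the values were 7.56 for C5ar1, 6.11 for Lad1, 4.76 for Cyp4a12b and 5.08 for Pdk4. Without replicate 1 that of Cyp4a12b was 6.42. The largest falls were Arl4c (-4.05, SE 0.18), Ccl2 (-3.86, SE 0.16), Rnase2a (-3.83, SE 0.20), Fcgr2b (-3.23, SE 0.12), the receptor tyrosine kinase gene Tyro3 (-3.20, SE 0.18), the chemerin receptor gene Cmklr1 (-3.20, SE 0.24; -4.10 without replicate 1 of Poly(I:C) with MSDC), Tent5c (-3.14, SE 0.10) and Ifi213 (-3.01, SE 0.29). Hif1a, which encodes a regulator of the response to low oxygen, differed by -0.06 (SE 0.06, adjusted p = 0.59).

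By list, 10 of 15 chemokines fell and 1 rose, with Ccl17 falling by 2.22 (SE 0.09), Cxcl16 by 2.71 (SE 0.15) and Ccl3 by 1.60 (SE 0.08). Of 15 NF-kB targets 7 fell and 1 rose (8 and 1 adjusted over the list alone), with Nfkbie falling by 1.20 (SE 0.10) and Icam1 by 0.65 (SE 0.06). Of 11 inflammasome genes 6 fell and 4 rose, and camera did not call that list (adjusted p = 0.902). Class I genes fell in 10 of 13 cases (11 adjusted over the list alone), B2m by 0.62 (SE 0.07) and H2-T22 by 0.71 (SE 0.08). H2-DMa (-1.61, SE 0.08) and H2-Aa (-1.57, SE 0.08) were among the class II falls. In the alternative activation list 5 of 9 fell and 1 rose, with Chil3 falling by 0.58 (SE 0.05). Among genes with higher values, 13 of 16 PPAR targets rose and 0 fell (edgeR; at an unadjusted p under 0.05 and with DESeq2 the counts were also 13 and 0), with Cidec rising by 3.27 (SE 0.08) and Plin2 by 1.96 (SE 0.06). Cholesterol synthesis rose in 19 of 22 genes (20 adjusted over the list alone), Hmgcs1 by 1.59 (SE 0.08) and Insig1 by 0.95 (SE 0.07). Fatty acid oxidation rose in 12 of 15 and fell in 1 (13 and 1 adjusted over the list alone), with Hadha rising by 0.87 (SE 0.06). Pyruvate handling rose in 8 of 15 and fell in 1 (9 and 1 adjusted over the list alone), with Mpc1 rising by 0.43 (SE 0.07) and Pdk1 by 0.59 (SE 0.09). Of the 24 identity genes 10 rose and 9 fell (10 and 12 adjusted over the list alone). Camera called that list higher although its median was -0.10, with a mean of 0.77.

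Camera adjusted p were 2.8e-44 for PPAR targets, 4.6e-21 for class II, 6.5e-18 for cholesterol synthesis, 6.7e-12 for identity, 2.2e-10 for chemokines, 2.3e-09 for fatty acid oxidation, 4.0e-05 for class I, 0.000113 for pyruvate handling, 0.000168 for interferon-stimulated genes, 0.00206 for alternative activation and 0.0157 for NF-kB targets. Class II (adjusted p = 0.0177) and PPAR targets (adjusted p = 0.0229) kept the call with an estimated correlation. The others had adjusted p = 0.0785 for cholesterol synthesis, 0.0882 for identity, 0.0942 for chemokines, 0.18 for fatty acid oxidation, 0.372 for class I, 0.165 for pyruvate handling, 0.73 for interferon-stimulated genes, 0.153 for alternative activation and 0.43 for NF-kB targets with an estimated correlation.

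Of the 874 genes that Poly(I:C) raised in vehicle, 422 were lower and 58 higher with MSDC in stimulated cells, against 119 and 109 for independent lists. Because both comparisons use the Poly(I:C) with vehicle libraries, part of this may come from them. In 20 simulations with the Poly(I:C) effect and no effect of MSDC, 1320 genes on average were called higher with Poly(I:C). Of these at most 4 were lower and at most 2 higher with MSDC, and their median change averaged -0.0326 against -0.284 observed for the 874. In unstimulated cells 310 of the 874 were lower and 114 higher with MSDC, in a comparison that shares the vehicle libraries with Poly(I:C) in vehicle. The counts were 108 and 97 for independent lists and at most 2 and 3 in the same simulations, and they were 266 and 109 without vehicle replicate 1 and 316 and 110 without vehicle replicate 2. The simulations let genes vary independently, so they leave out a shift of many genes within 1 library. They also took the observed group means as true, so they may understate what the shared libraries contribute. The MSDC effects at rest and under Poly(I:C) share no library. They had 1002 of the 1294 higher genes and 1109 of the 1440 lower genes in common, against 161 and 197 for independent lists, and 2 and 2 genes went opposite ways (Pearson's r = 0.745, Spearman's rho = 0.692 across 11621 genes).

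**Figure D1:**
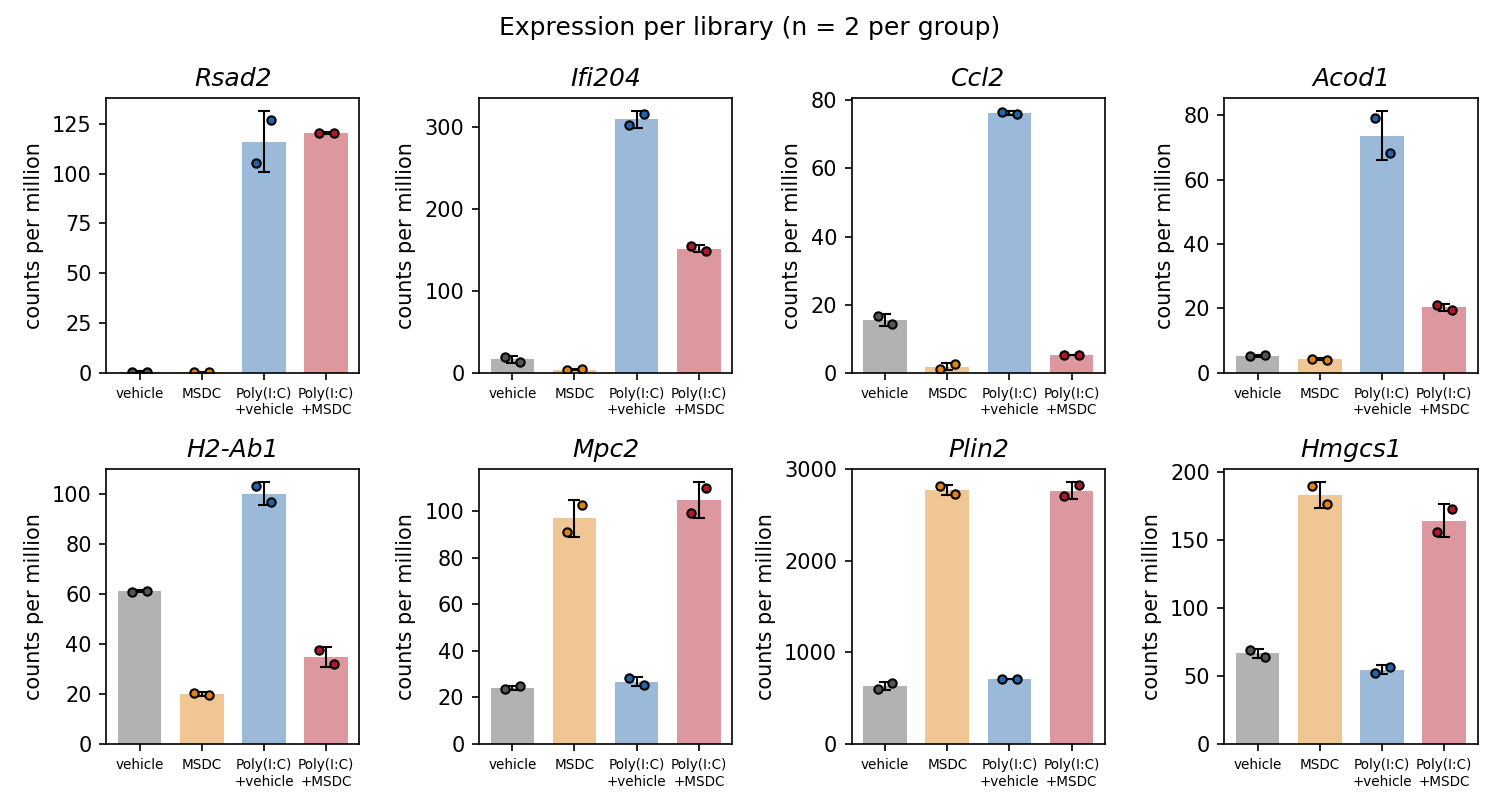
Levels (CPM) of 8 genes in the 4 groups; points are libraries, bars are means and error bars are SD (n = 2). Ccl2 reached 76.3 CPM with Poly(I:C) and vehicle and 5.25 CPM with Poly(I:C) and MSDC, whereas Rsad2 reached 116.1 and 120.5 CPM.

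**Figure D2:**
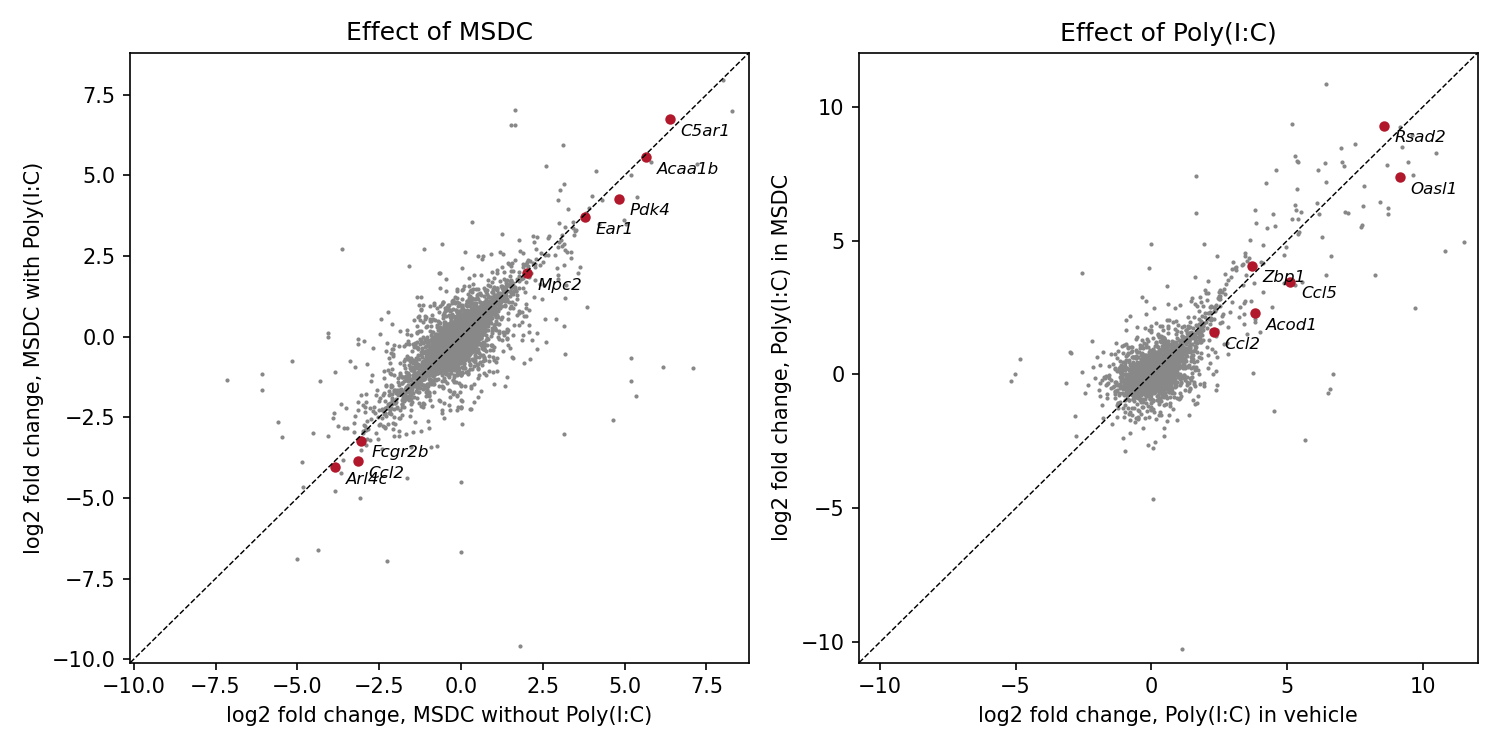
Log2 fold changes of 11621 genes, 1 point per gene. The left panel sets the effect of MSDC without Poly(I:C) (horizontal) against that with Poly(I:C) (vertical), and the right panel sets the effect of Poly(I:C) in vehicle (horizontal) against that in MSDC (vertical); dashed lines mark equal effects, and Pearson's r across genes was 0.745 and 0.762.

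The fifth comparison, the interaction, asked whether the response to Poly(I:C) differed between MSDC and vehicle. The Poly(I:C) response of Acod1 was smaller in MSDC by 1.54 on the log2 scale (SE 0.17, adjusted p = 0.000622), and that of Cfb, a complement component, by 0.85 (SE 0.08, adjusted p = 0.000158), since Cfb was already at 429.6 ± 7.82 CPM with MSDC alone and at 247.1 ± 7.40 CPM with vehicle and reached 1043 ± 11.3 and 1083 ± 49.2 CPM. The opposite held for Ifi27, which fell with Poly(I:C) in vehicle and went from 19.0 ± 1.95 to 38.5 ± 0.0787 CPM in MSDC (interaction 1.87, SE 0.19, adjusted p = 0.000354), and for the galectin gene Lgals9 (1.05, SE 0.12, adjusted p = 0.000622). In total 14 genes had a larger and 12 a smaller response in MSDC, 11 and 1 of them by at least 2-fold, and 756 had an unadjusted p under 0.05. With library totals alone the split was 14 and 4 (77.8% against 53.8% larger). DESeq2 gave 23 and 24, limma on log2 FPKM 6 and 22, and the fit without the expression filter 64 and 52. Larger and smaller responses numbered 23 and 39 without vehicle replicate 1, 56 and 33 without vehicle replicate 2, 3 and 2 without MSDC replicate 1, 12 and 3 without MSDC replicate 2, 10 and 5 without replicate 1 and 12 and 5 without replicate 2 of Poly(I:C) with vehicle, and 4 and 3 without replicate 1 and 4 and 2 without replicate 2 of Poly(I:C) with MSDC.

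The larger responses included interferon-inducible genes: Slfn5 (2.92, SE 0.47; 2.01 without vehicle replicate 1), Xaf1 (2.33, SE 0.34), Slfn8 (1.78, SE 0.26), Oas1a (1.23, SE 0.17), Ifi204 (1.20, SE 0.19), Irf9 (1.10, SE 0.18) and Dhx58 (0.98, SE 0.18). The smaller ones included Sema4d (-0.94, SE 0.17), the C-type lectin gene Clec4e (-0.72, SE 0.14), Selenow (-0.66, SE 0.10), Nt5c3 (-0.61, SE 0.11), Ass1 (-0.58, SE 0.09), H2-K1 (-0.44, SE 0.08) and H2-D1 (-0.43, SE 0.07). Each of these 14 lost its call in at least 2 of 15 alternatives. For Slfn5, Xaf1 and Ifi204 the larger response went with a lower resting level in MSDC, not with a higher stimulated level. At rest Slfn5 stood at 21.7 and 7.86 CPM in vehicle and at 1.2 and 2.1 CPM in MSDC. With Poly(I:C) it stood at 262 and 289 CPM in vehicle and at 228 and 240 CPM in MSDC. Xaf1 with Poly(I:C) stood at 55.7 and 58 CPM and at 43.4 and 44.9 CPM, and Ifi204 at 302 and 317 CPM and at 155 and 148 CPM. Tnf (-0.61, SE 0.14, adjusted p = 0.12) and Ccl2 (-0.72, SE 0.28, adjusted p = 0.698) were not called. Camera called 9 lists with its preset correlation and 0 with an estimated correlation. With the preset correlation it called the interferon-stimulated genes higher (median 0.37, adjusted p = 1.7e-09, and 0.509 with an estimated correlation). Of those 26 genes edgeR called 3 higher and 0 lower (8 and 4 adjusted over the list alone), DESeq2 3 and 2, and limma on log2 FPKM 1 and 3, with a median of 0.16. The edgeR median was -0.02 without vehicle replicate 1, 0.15 without MSDC replicate 1, 0.65 without vehicle replicate 2 and 1.13 without MSDC replicate 2. It also called RNA sensing (median 0.05, adjusted p = 0.00409), alternative activation (0.25, adjusted p = 0.0115) and the unfolded protein response (0.12, adjusted p = 0.000589) higher. It called cytokines (-0.54, adjusted p = 3.7e-09), NF-kB targets (-0.28, adjusted p = 1.4e-07), chemokines (-0.39, adjusted p = 4.3e-05), class I (adjusted p = 0.00119) and the inflammasome (-0.20, adjusted p = 0.00832) lower; the class I median was -0.02, and 0.01 with library totals alone.

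In the order given the 9 lists had adjusted p = 0.509, 0.492, 0.18, 0.215, 0.0706, 0.136, 0.196, 0.509 and 0.169 with an estimated correlation. Members called by edgeR were 1 of 12 for RNA sensing (3 adjusted over the list alone), 1 of 12 for cytokines (4 adjusted over the list alone) and 2 of 13 for class I (6 lower and 1 higher adjusted over the list alone). For chemokines, NF-kB targets, the inflammasome, alternative activation and the unfolded protein response the count was 0, with 7, 5, 5, 2 and 4 members at an unadjusted p under 0.05, and DESeq2 called 2, 0, 0, 1 and 0. PPAR targets, cholesterol synthesis and fatty acid oxidation also had 0 members called by edgeR, with 1 each at an unadjusted p under 0.05 and 0 called by DESeq2.

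**Figure D3:**
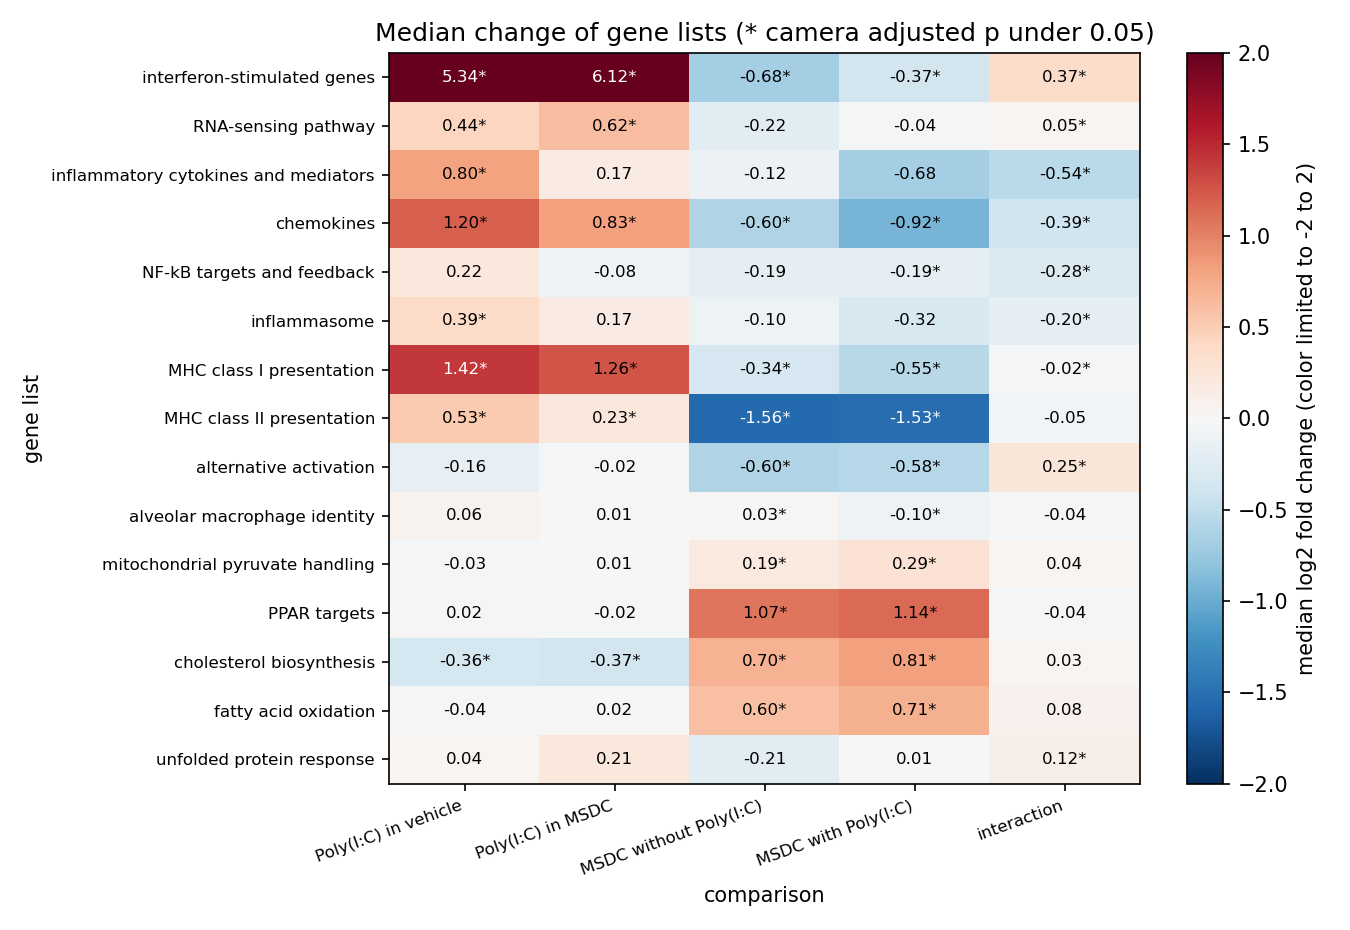
Median log2 fold change of 15 gene lists (vertical) in the 5 comparisons (horizontal), as numbers and colors limited to -2 to 2; an asterisk marks a camera adjusted p under 0.05 with the preset correlation. The class II medians were -1.56 and -1.53 for MSDC without and with Poly(I:C); the alveolar macrophage identity median turns from 0.03 to -0.01, and that of class I in the interaction from -0.02 to 0.01, with library totals alone.

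Markers of other cells moved with MSDC as well. Of 7 monocyte and interstitial macrophage markers 3 fell at rest and 3 under Poly(I:C), with Cd14 at 16.5 ± 0.284 and 6.51 ± 0.204 CPM at rest and at 18.4 ± 0.779 and 6.08 ± 1.17 CPM with Poly(I:C), and Ccr2 falling by 2.11 (SE 0.32) and 1.79 (SE 0.31). The dendritic cell markers Zbtb46 and Clec9a also fell in both states, and the 8 markers of that list summed to 9.99 CPM in vehicle, 5.79 in MSDC, 14.5 in Poly(I:C) with vehicle and 8.10 in Poly(I:C) with MSDC. Mmp8, listed as a neutrophil marker, fell by 2.60 (SE 0.25) at rest and by 1.82 (SE 0.23) under Poly(I:C), and S100a8 was at 4.66 ± 0.925 and 7.09 ± 0.920 CPM at rest. Without replicate 1 of Poly(I:C) with MSDC the changes under Poly(I:C) were -2.50 for Mmp8 and -2.43 for Ccr2. The resting calls of Clec9a (without MSDC replicate 1), S100a8 and Cdh1 were each lost without at least 1 library. The epithelial list summed to 76.3, 61.1, 53.4 and 48.8 CPM in the same order of groups, nearly all of it Cdh1, which fell with Poly(I:C) in vehicle (-0.53, SE 0.08). The T and NK cell list summed to 141, 97.0, 138 and 80.5 CPM, nearly all of it Cd2, and the B cell list to 168, 149, 165 and 144 CPM, nearly all of it Cd22. Stromal and endothelial markers summed to at most 3.88 CPM, erythroid markers to at most 0.0348 and the listed interferons to at most 0.0528 CPM. Of 25 ribosomal protein genes, read as a sign of RNA quality, 1 fell with Poly(I:C) in vehicle (Rpl23, -0.29, SE 0.08) and 1 with MSDC under Poly(I:C) (Rplp0, -0.18, SE 0.06), calls that were lost in 3 and 8 of 16 alternatives. Such calls between groups do not show differences in quality between replicates. The difference between replicates correlated with gene length with Spearman's rho = 0.4 in vehicle and 0.285 in MSDC. It was -0.07 in Poly(I:C) with vehicle and 0.00134 in Poly(I:C) with MSDC.

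The other lists were LXR targets and fatty acid synthesis, glycolysis, HIF-1 targets, the TCA cycle, oxidative phosphorylation, the integrated stress response, NRF2 targets, heat shock and immediate early genes, lysosome, cell cycle and ribosomal proteins. With the neutrophil, epithelial, monocyte and dendritic markers these 15 lists gave 75 tests, of which camera called 0, with a smallest adjusted p of 0.0727 and 7 at an unadjusted p under 0.05. Fry, which asks whether the genes of a list move on balance without comparing them with other genes, called 19 of the 75, and 49 when it allowed members to move in either direction. Single members were called in many of these lists, such as 10 higher and 1 lower of 25 cell cycle genes and 7 higher and 3 lower of 17 NRF2 targets with MSDC at rest.

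Positions on GRCm38 of the genes named most often, all protein-coding in the annotation, are as follows. Mpc1 (gene ID 55951) lies on chromosome 17 from 8283787 to 8297667 and Mpc2 (70456) on chromosome 1 from 165461260 to 165481218. Acod1 (16365) lies on chromosome 14 from 103047012 to 103056573, Ccl2 (20296) on chromosome 11 from 82035577 to 82037452, Pdk4 (27273) on chromosome 6 from 5483351 to 5496278, C5ar1 (12273) on chromosome 7 from 16246743 to 16259540 and H2-Ab1 (14961) on chromosome 17 from 34263227 to 34269418.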

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

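The interaction, a planned test of whether the response to Poly(I:C) differs between MSDC and vehicle, picked out every result of this part, and the 2 tests that weigh explanations were chosen after the result was seen. Groups of 2 samples allow no test for a sample far from the others.

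In total 14 genes had a larger and 12 a smaller response in MSDC. Among the larger were Slfn5 (2.92), Xaf1 (2.33), Ifi27 (1.87), Slfn8 (1.78), Oas1a (1.23), Ifi204 (1.20), Irf9 (1.10), Lgals9 (1.05) and Dhx58 (0.98). Among the smaller were Acod1 (-1.54), Sema4d (-0.94), Cfb (-0.85), Clec4e (-0.72), Selenow (-0.66), Nt5c3 (-0.61), Ass1 (-0.58), H2-K1 (-0.44) and H2-D1 (-0.43). Of these 18 genes only Ifi27, Lgals9, Acod1 and Cfb kept the call in each of the alternatives run. By list, the median difference was 0.37 for interferon-stimulated genes, 0.0451 for RNA sensing, 0.25 for alternative activation and 0.12 for the unfolded protein response. It was -0.54 for cytokines and mediators, -0.39 for chemokines, -0.28 for NF-kB targets, -0.20 for the inflammasome and -0.0191 for MHC class I (0.0125 with library totals alone). None of these lists kept its call when the correlation between genes was estimated (adjusted p from 0.0706 to 0.509).

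The larger response of interferon-stimulated genes in MSDC may come from 1 resting library: their median was 0.37 with all libraries and -0.0186 without vehicle replicate 1, and 0.653 without vehicle replicate 2, 0.147 without MSDC replicate 1 and 1.13 without MSDC replicate 2. It was 0.159 with limma on log2 FPKM, which called 1 of these genes higher and 3 lower. With all libraries the median change of these genes with MSDC was -0.682 at rest and -0.371 under Poly(I:C). Of the 26 genes edgeR called 0 higher with MSDC in either state. Irf7, shown after its values were seen, stood at 15.5 and 6.24 CPM in the vehicle replicates and at 1.69 and 4.22 CPM in the MSDC replicates. Gene length bias was argued against as the whole cause, since the median was 0.398 after the trend on length had been removed. The interaction still correlated with length (Spearman's rho = 0.23 over 10777 genes). So did the difference between the vehicle replicates (0.4) and that between the MSDC replicates (0.285). A biological difference between MSDC and vehicle in the resting interferon state stays open, as does a difference between the cultures, and neither can be decided with 2 samples per group.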

How the results depend on the processing

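Of the settings in this part, limma on log2 FPKM and scaling by library totals alone were chosen after seeing the data. The others were planned. Apart from a fixed set, the named genes had been picked in the main fit for a large change or a small p, which favours their keeping a call. No called value of a named gene changed its direction: over 376 results of named genes, 244 of them called, and 16 settings there were 5834 values, of which 5638 stayed on the same side of the threshold, 144 lost the call, 52 gained it and 0 were reversed. Of the 244 calls, 209 were never lost.

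Requiring a 2-fold change as well gave 293 higher and 12 lower for Poly(I:C) in vehicle, 230 and 2 for Poly(I:C) in MSDC, 258 and 377 for MSDC without Poly(I:C), 279 and 399 for MSDC with Poly(I:C), and 11 and 1 for the interaction, because the threshold is stricter. Fitting only the groups of a comparison gave 257 lower genes for Poly(I:C) in vehicle and 415 for Poly(I:C) in MSDC. Without a filter 298 genes were lower for Poly(I:C) in MSDC, and the interaction had 64 higher and 52 lower. DESeq2 gave 23 and 24 for the interaction. Limma on log2 FPKM gave 751 lower for Poly(I:C) in vehicle and 6 and 22 for the interaction, and library totals alone gave 867 lower and, for the interaction, 14 and 4. Limma on log2 FPKM adds 1 to each value and so gave smaller folds for genes at low levels, such as 2.42 for Cyp4a12b at rest. With an estimated correlation 8 of the 44 calls of gene lists were kept. The cause was not tested except for the threshold.

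Leaving out 1 library leaves a group with 1 sample, which is assumed to vary like the other groups. Calls also moved when the library left out was in neither group of a comparison, since spread and scaling are estimated over all libraries. For Poly(I:C) in vehicle the counts ranged from 654 to 982 higher and from 210 (without replicate 1 of Poly(I:C) with vehicle) to 670 lower. For Poly(I:C) in MSDC they ranged from 351 (without MSDC replicate 2) to 729 higher and from 50 (without MSDC replicate 1) to 421 (without vehicle replicate 2) lower, with 331 without vehicle replicate 1, 63 without MSDC replicate 2, and 77 and 54 without replicates 1 and 2 of Poly(I:C) with MSDC. For MSDC they ranged from 849 (without MSDC replicate 1) to 1355 higher and 969 to 1547 lower without Poly(I:C), and from 1012 to 1711 higher and 1144 to 1954 lower with Poly(I:C). For the interaction they ranged from 3 (without MSDC replicate 1) to 56 (without vehicle replicate 2) higher and from 2 (without MSDC replicate 1 or replicate 2 of Poly(I:C) with MSDC) to 39 (without vehicle replicate 1) lower, and each of the 8 libraries moved at least 1 of these 2 counts by over 1.5 times.

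With a replicate block the counts were 860 and 440, 543 and 149, 1232 and 1388, 1406 and 1535, and 16 and 8 in the order of the comparisons, and 44 list tests were called. These shared 1270 of 1351, 687 of 734, 2592 of 2734, 2907 of 3036 and 21 of 26 genes with the unpaired fit. Planned settings that apply to FPKM alone (pseudocounts of 0.1 and 5, quantile normalization, no mean trend) were not run, because counts were used. Ifnb1 and Il6 stayed at or under 4 counts in each library and were not tested.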

Other observations

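The gene families in this part and the 5 tests that weigh explanations were all chosen after the results were seen, so each pattern here is a hypothesis.

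The PYHIN genes, which encode sensors of nucleic acids and related proteins, lie side by side on chromosome 1, from Aim2 at 173349547 to Ifi205 at 174031755. All 11 tested members rose with Poly(I:C) in vehicle, and with MSDC under Poly(I:C) 10 were lower and Aim2 was not called (0.01, adjusted p = 0.964). Camera gave an adjusted p of 1.37e-13 for the family and 0.0505 with an estimated correlation. Summed levels went from 1435 ± 72.5 to 793 ± 49.1 CPM (SD, n = 2), a log2 ratio of -0.856 with Aim2 included. This was near the median of -0.74 of 134 other genes induced at least 4-fold. The measures are unlike, since a ratio of sums weighs abundant members most and a median counts each gene alike. Reads could be split between these similar genes, which alters the values of members but not their sum. The 10 members induced at least 4-fold had a median change of -1.60 with MSDC, from -0.456 (Ifi207) to -3.01 (Ifi213). Of the 134 other genes 76 were lower, 1 was higher and 57 were not called. Ifit1 (0.13, SE 0.14), Cmpk2 (-0.13, SE 0.16) and Oas2 (0.08, SE 0.19) were among those not called, and Irf7 fell by 1.12 (SE 0.20). All 8 guanylate-binding protein genes were lower with MSDC under Poly(I:C) (adjusted p = 5.13e-05, and 0.0816 with an estimated correlation), as were 6 of 8 Schlafen genes (adjusted p = 2.16e-05, and 0.0721 with an estimated correlation), with Slfn1 at 72.7 and 9.19 CPM. Part of this was present at rest, where 7 guanylate-binding protein genes (median -1.25, against -0.79 under Poly(I:C)), 5 PYHIN genes (median -1.19; 1 higher) and 5 Schlafen genes (median -0.62) were lower, with adjusted p = 0.0628, 0.199 and 0.162 with an estimated correlation. The resting medians were -1.13, -0.923 and -0.476 without vehicle replicate 1, and -0.56, -0.0123 and -0.375 with limma on log2 FPKM. The median interaction of the guanylate-binding protein genes was 0.34 with 1 of 8 genes called (adjusted p = 0.0384 with an estimated correlation), 0.204 without vehicle replicate 1 and -0.0637 with limma on log2 FPKM, so a difference in their response stays open.

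Receptors and proteases of macrophages moved apart with MSDC. Of 5 genes for Fc gamma receptors and their shared chain Fcer1g (-0.65, SE 0.08), 4 were lower and 1, Fcgr4, was higher (0.96, SE 0.09) under Poly(I:C) (adjusted p = 0.0209 with an estimated correlation). Of 9 matrix metalloproteinase genes 7 were lower at rest and 6 under Poly(I:C) (adjusted p = 0.017 and 0.0127 with an estimated correlation), and Mmp12 went from 4471 to 604.5 CPM at rest. C5ar2, the second C5a receptor, was higher at rest (3.45, SE 0.19) and under Poly(I:C) (3.14, SE 0.19), while C3ar1 (-2.27, SE 0.24, and -2.21, SE 0.22) and Cfp (-1.83, SE 0.07, and -1.63, SE 0.07) were lower. These 3 belong to a list of 9 complement genes and C5a receptors in which 3 were higher and 2 lower at rest (adjusted p = 0.00219, and 0.0552 with an estimated correlation) and 2 higher and 4 lower under Poly(I:C) (adjusted p = 0.115, and 0.213 with an estimated correlation), so that list was not called under Poly(I:C). Of 16 genes of peroxisomal beta-oxidation 10 were higher at rest and 11 under Poly(I:C) (adjusted p = 0.0209 for both with an estimated correlation), with Pex11a at 12.2 and 72.5 CPM at rest.

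The rise of lipid genes with MSDC was weighed against 2 technical explanations. Gene length bias was argued against, since the change with MSDC under Poly(I:C) correlated only weakly with length (Spearman's rho = 0.0976 over 10777 genes). The median of the 16 PPAR targets was 1.14 both before and after the trend on length had been removed. With so weak a trend, its removal could hardly have lowered that median. RNA of epithelial cells was argued against as well, since Sftpc, an abundant transcript of alveolar epithelium, stood at 0.0176 and 0.0175 CPM with Poly(I:C) and vehicle and with Poly(I:C) and MSDC, and Scgb1a1 at 0.123 and 0.174 CPM. All 12 epithelial markers, mostly Cdh1, summed to 53.4 and 48.8 CPM, the latter being 0.642% of the summed rise of the 13 PPAR targets that rose (7613 CPM). An effect of MSDC on PPAR target genes may explain the rise, and no test here separates it from other actions of the compound.

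The lower class II genes and the lower Acod1 with MSDC in stimulated cells were weighed in the same way. Fewer monocytes, interstitial macrophages or dendritic cells may contribute and stay open: the 11 tested markers of those cells had a median change of -0.895, and Cd14 (18.4 to 6.08 CPM), Ccr2 (4.17 to 1.20), Zbtb46 (2.34 to 0.976) and Clec9a (10.6 to 5.47) fell by 0.95 to 1.79 on the log2 scale beside a class II median of -1.53, while the other tested markers included C1qb (1.43 to 1.32 CPM), C1qc (0.944 to 0.958), Fscn1 (1.03 to 1.05) and Ccr7 (0.244 to 0.453), which were not called. A weaker Poly(I:C) response could not account for the class II genes, since 9 of 9 were lower with MSDC in both states. The Poly(I:C) response of Acod1 itself was smaller in MSDC (interaction -1.54). Whether a weaker response of the cells to Poly(I:C) lay behind it cannot be told from the interferon-stimulated genes. Their median change with MSDC was -0.371 under Poly(I:C) and -0.682 at rest. Their median interaction was 0.37, and -0.0186 without vehicle replicate 1, and it is not known whether they were saturated. A direct effect of MSDC on these genes may explain them and was not tested.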
